A study of Homo sapiens with 6 samples.

How the data were processed

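ATAC-seq libraries from NB4 cells were grouped by their titles into 4 groups: control and SMARCD2 knockdown, each in DMSO and in 1 µM all-trans retinoic acid (ATRA). Each treatment had 1 control library and 2 knockdown libraries, 1 per hairpin (shRNA1 and shRNA2), so the hairpins served as the replicates of the knockdown. Nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The free-text description of the DMSO control library names ATRA, while its title, its stage label and the matching column name give DMSO, and the title was followed. Libraries were made from 50000 cells per condition, per the labels' protocols.

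Per the submitters' processing notes, bcl2fastq, STAR, Picard 2.5.0, MACS2 and edgeR were used with the human build GRCh37.p13. Their roles, the peak calling per library or on pooled reads, the handling of the Tn5 offset and of mitochondrial or duplicate reads, and the settings are not given in the sources used here. Each treatment has 1 table of regions. Per the file headers, the authors gave raw read counts per region and library, and these whole numbers were used as deposited. The normalized counts, a signal in the deposited tables, are the raw counts multiplied by 1 constant factor per library, and how the authors set that factor is not given in the sources used here. The authors' log2 fold change (knockdown over control), mean log2 CPM and F score are named in the file headers as in a quasi-likelihood test table of edgeR. The deposited p-value column is unadjusted. The largest p in the tables is 0.00499 in DMSO and 0.00498 in ATRA, and the largest distance to the nearest gene is 9992 bp, so the tables hold regions with p under 0.005 and a gene within 10 kb, and regions outside those limits were not analysed here. The smallest mean log2 CPM is -0.974 in DMSO and -0.997 in ATRA, so a lower limit on abundance may also have been applied. The simulations of unchanged regions used no such limit.

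The selection by p decides what the tables can show. A region is listed because its libraries differed, so the listed fold changes lean towards large values, a test repeated on the listed regions is not independent evidence, and no share of all accessible regions can be given. Enrichment of gene lists was not tested for the same reason.

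Library totals are not columns of the tables. The plan fixed before the data were examined assumed that they would be, and effective library sizes were instead recovered from the authors' fold changes and mean abundances by least squares. The recovered sizes gave back the authors' log2 fold changes with a largest deviation of 0.021 in DMSO and 0.0060 in ATRA. They were 12788000 reads (shRNA1), 15739000 (shRNA2) and 11520000 (control) in DMSO, and 16178000, 18756000 and 14390000 in ATRA. The scale of the authors' normalized counts differs from that of their fold changes by a constant 0.18 log2 units in DMSO and 1.01 in ATRA. A ratio of knockdown to control is therefore 1.13 times smaller in DMSO and 2.01 times smaller in ATRA on the normalized count scale. The fold change scale was used as the main scale and the normalized count scale as an alternative.

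The main test was edgeR 4.0.16 (quasi-likelihood, in R 4.3.3) on the raw counts with the recovered library sizes, a minimum of 10 reads in a library of median size (filterByExpr), and Benjamini-Hochberg adjustment over the listed regions alone with a threshold of 0.05. With 1 control and 2 knockdown libraries the fit has 1 residual degree of freedom per region, and the spread between control cultures is not measured. DESeq2 1.42.0 was run as an alternative, with its own size factors from the listed regions, which changes the scale as well as the test, and at the recovered library sizes. In simulated tables of the same size, the test called 16 of 30 regions changed 4-fold, 26 of 30 changed 8-fold and 1 of 263 unchanged regions for DMSO, and 13 of 30, 22 of 30 and 0 of 208 for ATRA. Those tables had a dispersion of 0.05, no count filter and no selection by p. The rates therefore do not carry over to the listed regions. The number of regions the authors tested was inferred from the relation between their F and p, which depends on the pooled residual degrees of freedom. It came to 54588 in DMSO and 49696 in ATRA, and on 50000 simulated unchanged regions the same relation returned 50000. Adjusted p-values over that number count the listed regions alone, so they are upper bounds: regions farther than 10 kb from a gene were not analysed here, and the ranks of the listed regions among all tested could be higher with them.

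Ratios of reads are given over the summed knockdown reads against the control reads, each scaled by library size, with 95% exact intervals. Where the control had 0 reads the ratio is a lower bound against a floor of 3 reads in the control library. It takes the knockdown reads as counted, so it is not a 95% limit, and the exact lower limit, which also covers the knockdown reads, is smaller. Intervals and floors cover counting error only, since reads are not independent molecules. Normalized counts are given as the mean ± SD of the 2 knockdown libraries beside the control value, which has no SD. Directions were compared between classes of regions by two-sided Fisher's exact tests, and regions were called shared between treatments when they overlapped by at least 1 bp. Correlations used 100000 permutations. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

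The regions named were fixed by rule before the data were examined: per treatment, the 12 regions with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold with both hairpins in the same direction, 1 per gene; regions of genes in 17 lists (535 genes) past the threshold, up to 6 per list; genes listed under both treatments; and any region of SMARCD2. This gave 88 regions of 76 genes, of which 1 region is not reported here. The lists cover azurophil granules, specific granules, gelatinase and secretory granules, NADPH oxidase, retinoic acid response, haematopoietic transcription factors, the BAF complex, progenitors, monocytes and macrophages, erythroid cells, megakaryocytes and platelets, eosinophils, basophils and mast cells, lymphoid cells, chemokines and cytokines, interferon response, adhesion and cytoskeleton, and cell cycle. Of 569 gene symbols in the tables, 551 are current in a RefSeq table of GRCh38.p14 and 18 are older names. That table was used for names alone, and no exon or intron assignment was made, because its build is not that of the coordinates.

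Alternatives were a stricter threshold, a minimum fold change, an abundance filter, no count filter, DESeq2, genes in place of regions, autosomes alone, other overlap rules and leaving out each hairpin. Chosen after the data were seen were the normalized count scale, adjustment over the inferred number of tested regions, DESeq2 at the recovered library sizes, and regions with at least 1 control read. The knockdown by treatment interaction was also added after the data were seen, on the 2 regions listed in both treatments, as an edgeR quasi-likelihood test over the 6 libraries with the negative binomial dispersion held at 0.0422, the mean of the values estimated from the 2 lists. It was run without and with the hairpin as a block. The ATRA against DMSO contrast was not run, because the treatments were normalized in separate tables of different regions.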

Results

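Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open chromatin. The cells were NB4, a human acute promyelocytic leukaemia line that differentiates towards granulocytes in all-trans retinoic acid (ATRA). They carried a control or a short hairpin RNA (shRNA1 or shRNA2) against SMARCD2, a subunit of the BAF (SWI/SNF) chromatin remodelling complexes, and were kept in DMSO or in 1 µM ATRA. Each treatment had 1 control and 2 knockdown libraries. The tables list 323 regions in DMSO and 268 in ATRA, each with an unadjusted p under 0.005 in the authors' test. In DMSO the listed regions held 12185 reads (shRNA1), 12982 (shRNA2) and 11001 (control), and in ATRA 10456, 11371 and 5530. The median width was 141 bp in DMSO and 149 bp in ATRA. SMARCD2 itself had 0 listed regions, so the knockdown was not checked at its own locus here, and ATAC-seq does not measure its transcript.

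The DMSO libraries address which regions differ in accessibility when SMARCD2 is depleted in undifferentiated cells. Of the 323 regions, nearest to 319 genes, 213 had higher accessibility in the knockdown than in the control and 110 lower, or 65.9% higher (95% Clopper-Pearson interval 60.5% to 71.1%). Simulated unchanged regions that passed the same p, with 2 libraries set against 1, were 56.9% higher. The split depended on control coverage: with at least 1 control read 101 regions were higher and 110 lower (47.9% higher). With at least 20 control reads, 21 were higher and 80 lower. Both classes were chosen after the data were seen, by the control reads on which the direction also rests. The higher regions with the largest fitted change had 0 control reads. A region 773 bp from FRRS1, which codes for a ferric-chelate reductase (chromosome 1, 100232123 to 100232294, GRCh37.p13), had 25 reads with shRNA1 and 18 with shRNA2 and was at least 5.79-fold higher against the floor of 3 control reads (95% exact lower limit 4.51). A region in HDAC9, a class IIa histone deacetylase gene (chromosome 7, 18183903 to 18184064), had 7 and 28 reads and was at least 4.71-fold higher. A region in FYB, an adaptor of immune cell adhesion, had 19 and 10 reads and was at least 3.90-fold higher. Other regions of this group lay in or near YRDC, KIAA1024L, NIPSNAP3B, TSPYL1, LANCL1, MYH13, ABLIM1 and FAM65A, with bounds from 4.71-fold down to 3.90-fold.

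Among the lower regions in DMSO named by the rule, a region 1996 bp from TOMM5, a subunit of the mitochondrial import translocase, had 2 reads with each hairpin against 19 in the control and was 11.8-fold lower (95% counting interval 3.91 to 47.5). The authors' log2 fold change was -3.47 there, and lower still at CACNA1A (-3.83) and SYTL2 (-3.73), which the rule left out. A region in NEO1, which codes for the netrin receptor neogenin, was 9.91-fold lower (3.20 to 40.7), and a region 7570 bp from MMP12, the macrophage elastase gene, was 8.42-fold lower (2.98 to 29.2). A region 746 bp from SUV420H1, a histone H4 lysine methyltransferase gene now named KMT5B, was 7.43-fold lower (2.82 to 22.9). A region in ENTPD1, the ectonucleotidase CD39, was 7.02-fold lower (2.64 to 21.7), and so was a region 4243 bp from TMSB4X, the actin-binding thymosin gene, where shRNA1 had 6 reads and shRNA2 had 0 against 17. Regions at STEAP1B, GAD1, AASS, C19orf12, ARHGAP18 and P2RX4 were between 8.25-fold and 6.60-fold lower.

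Of the 535 genes in lists fixed before the data were examined, 10 had a listed region in DMSO, 8 higher and 2 lower. All 10 passed edgeR's quasi-likelihood test adjusted over the listed regions, which were themselves selected by p. In DMSO 261 of all 303 regions kept by the count filter passed it, so the pass adds little. With DESeq2, or adjusted over the implied number of tested regions with ranks among the listed regions alone, 0 DMSO regions passed. In the azurophil granule list, 2 of 24 genes were listed and both were higher. The region 3908 bp from AZU1, which codes for the granule protein azurocidin, had 20 and 15 reads against 1 in the control and was 14.1-fold higher (2.38 to 574). The region in PLAC8 held 23.8 ± 4.89 normalized counts in the knockdown (SD, n = 2) against 6.00 in the control. It was 4.52-fold higher on the fold change scale (1.83 to 14.5) and 3.99-fold on the normalized count scale. In the gelatinase and secretory granule list 1 region, in MGAM, was 7.27-fold higher (1.87 to 62.3). In the monocyte and macrophage list 1 region, 5903 bp from CIITA, the transactivator of MHC class II genes, held 21.5 ± 5.87 normalized counts (SD, n = 2) against 1.20 from 1 control read. It was 20.2-fold higher on the fold change scale (3.46 to 813) and 17.8-fold on the normalized count scale. Among haematopoietic transcription factors a region in TCF7L2, a Wnt pathway factor, was 6.87-fold higher (2.22 to 34.4). A region in SMAD3, a TGF-beta signal transducer from the retinoic acid response list, was 4.04-fold higher (1.75 to 11.4), and a region in ARHGAP25, a Rac GTPase-activating protein gene of phagocytes, was 3.49-fold higher (1.86 to 7.22). In the lymphoid list the region near CD5 had 0 control reads and was at least 2.69-fold higher.

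Both list members lower in DMSO belong to the BAF complex list, where 2 of 30 genes were listed. The region in GLTSCR1 (now BICRA), a subunit of the noncanonical BAF complex (chromosome 19, 48167228 to 48167342), held 8.62 ± 2.84 normalized counts (SD, n = 2) against 42.0. It was 4.33-fold lower on the fold change scale (2.43 to 7.92) and 4.92-fold on the normalized count scale. On the fold change scale edgeR's quasi-likelihood test gave an adjusted p = 0.00280 over the listed regions. The region in BCL7A, another BAF subunit gene (chromosome 12, 122492318 to 122492510), held 21.2 ± 5.01 normalized counts (SD, n = 2) against 62.4. It was 2.58-fold lower on the fold change scale (1.71 to 3.88, edgeR quasi-likelihood adjusted p = 0.00570) and 2.92-fold on the normalized count scale. Neither passed DESeq2 (adjusted p = 0.129 for both). Neither passed the adjustment over the implied number of tested regions with ranks among the listed regions alone (adjusted p at most 0.534 and 0.695).

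**Figure D1:**
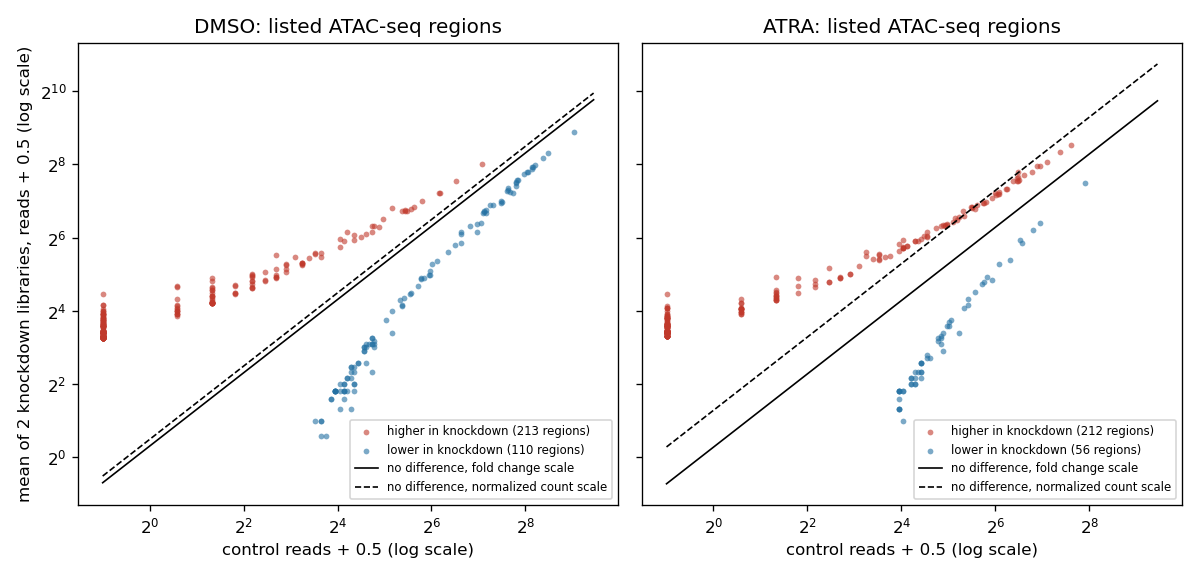
Reads in each listed region, control library on the x axis against the mean of the 2 knockdown libraries on the y axis (both plus 0.5, log scales), for DMSO (left) and ATRA (right). Points are regions, red for higher and blue for lower in the knockdown, and the lines mark no difference on the fold change scale (solid) and on the normalized count scale (dashed), which lie 0.18 log2 units apart in DMSO and 1.01 in ATRA.

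In DMSO, edgeR's quasi-likelihood test called 261 of 303 regions kept by the count filter, 171 higher and 90 lower, at an adjusted p under 0.05 over the listed regions alone, which were themselves selected by p, and 314 (206 higher, 108 lower) on the normalized count scale. The count filter was applied again at the library sizes of that scale, so the regions tested there were not the same 303. Adjusted over the 54588 regions that the authors' F and p imply were tested, 0 regions passed (smallest adjusted p at most 0.439, counting the listed regions alone, with all 323 at an unadjusted p under 0.005), and DESeq2 called 0 with its own size factors (81 at an unadjusted p under 0.05) and 0 at the recovered library sizes (74).

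The ATRA libraries address the same question in differentiating cells. Of the 268 regions, nearest to 261 genes, 212 were higher in the knockdown and 56 lower, or 79.1% higher (95% Clopper-Pearson interval 73.7% to 83.8%), against 62.6% of simulated unchanged regions that passed the same p. On the normalized count scale the split was 185 higher and 83 lower (69.0%), with 27 regions on the other side of 0, and in ATRA a fold higher is 2.01 times smaller and a fold lower 2.01 times larger on that scale. The largest higher change was 97 bp from GPR153, an orphan receptor gene (chromosome 1, 6321133 to 6321247), with 28 and 15 reads against 0, at least 5.90-fold higher (at least 2.94-fold on the normalized count scale). A region in PIP4K2A, a phosphoinositide kinase gene, was at least 4.67-fold higher, a region in the NADPH oxidase gene NOX5 at least 4.26-fold, and regions in TGFBR2, a TGF-beta receptor gene, and STAT4, a cytokine signalling factor, at least 3.84-fold. PITPNC1, CCER1, SCN2A, YOD1, PDE2A, ZFP69 and SRD5A3 had bounds from 4.53-fold down to 3.84-fold. All 12 had 0 control reads.

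The largest lower change in ATRA was in DLG2, a scaffold protein gene (chromosome 11, 83773397 to 83773471), with 0 and 3 reads against 16, 12.9-fold lower (3.71 to 69.3). Regions in HM13, the signal peptide peptidase gene, and TRPC6, a cation channel gene, each had 0 and 4 reads against 15 and were 9.10-fold lower (2.90 to 37.7). A region in AKAP13, a kinase anchoring protein gene, was 6.59-fold lower (2.65 to 18.5), and a region 204 bp from SEMA3A, a semaphorin gene, was 6.47-fold lower (2.41 to 20.2). Regions at LSMEM1, MYO3B, PXDC1, ETV3L, NT5C1A and GIPC1 were between 9.10-fold and 6.24-fold lower.

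In ATRA, 10 list genes had 11 listed regions, 8 higher and 3 lower. In the erythroid list 2 of 21 genes were listed, both higher. The region in CA2, carbonic anhydrase 2 (chromosome 8, 86376018 to 86376597), was the best covered, with 50 and 72 reads against 16, 3.14-fold higher (1.86 to 5.67; edgeR quasi-likelihood, adjusted p = 0.00644), but 1.56-fold on the normalized count scale, where the adjusted p of the same test was 0.240. The region in TFRC, the transferrin receptor gene, was at least 3.02-fold higher. A region in CEBPD, a myeloid transcription factor gene, was at least 2.88-fold higher, and a region in E2F1, a cell cycle transcription factor gene, 3.71-fold (1.70 to 9.60; on the normalized count scale 1.85-fold, edgeR adjusted p = 0.287). In the adhesion list ITGA6, an integrin gene, was 13.2-fold higher (2.20 to 537; on the normalized count scale 6.57-fold, edgeR adjusted p = 0.0942) and ARHGAP15 at least 3.16-fold. In the BAF list the region 7542 bp from BCL7A was at least 2.75-fold higher, while the region in DPF3, another BAF subunit gene, held 4.53 ± 0.332 normalized counts (SD, n = 2) against 42.1 and was 4.65-fold lower on the fold change scale (2.22 to 10.3) and 9.34-fold on the normalized count scale (4.46 to 20.6). In the interferon response list the region 7718 bp from BST2, the antiviral protein tetherin, was 6.47-fold lower (2.41 to 20.2). CD247, the T cell receptor zeta chain gene of the lymphoid list, had a region 5.77-fold lower (2.41 to 15.2) and another at least 2.61-fold higher against the floor. The exact lower limit of that higher region was 1.92 on the fold change scale. On the normalized count scale it was 0.958, so no change lies within that interval. For TFRC, CEBPD, ARHGAP15 and BCL7A, also with 0 control reads, the exact lower limits on the normalized count scale were from 1.01 (BCL7A) to 1.18 (ARHGAP15). Over both treatments, 6 of the 17 lists had 0 regions: specific granule, NADPH oxidase, progenitor, megakaryocyte and platelet, eosinophil, basophil and mast cell, and chemokines and cytokines. NOX5, named above, is not a member of the NADPH oxidase list.

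**Figure D2:**
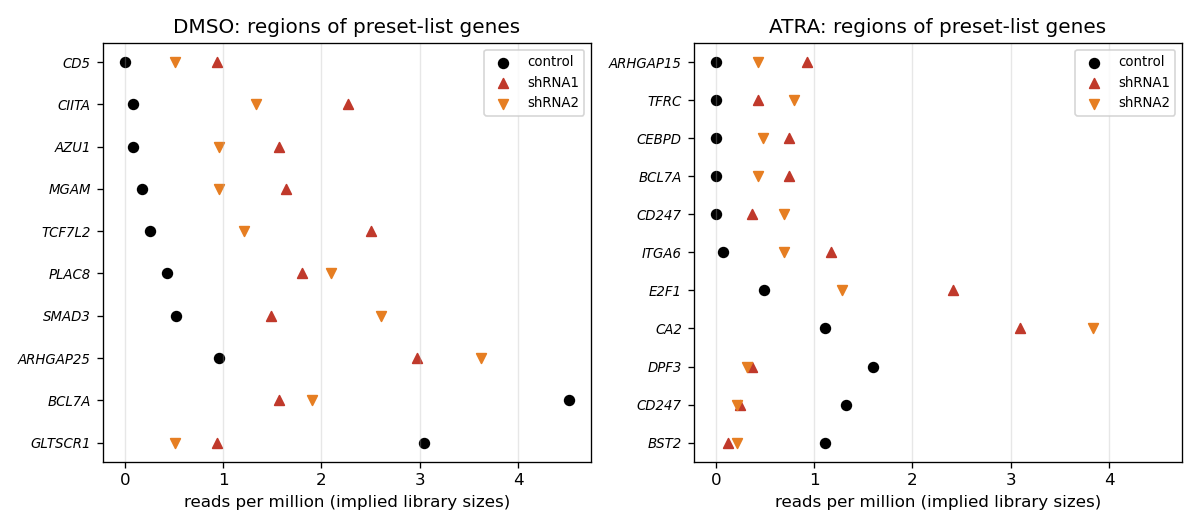
CPM, by the recovered library sizes, in each listed region of a preset-list gene, for DMSO (left, 10 regions) and ATRA (right, 11 regions). Black circles are the control library and triangles the libraries of shRNA1 (red) and shRNA2 (orange); in each row both knockdown libraries lie on the same side of the control.

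In ATRA, edgeR's quasi-likelihood test called 257 of 257 regions kept by the count filter, 201 higher and 56 lower, over the listed regions alone, and 148 (91 higher, 57 lower) on the normalized count scale. For that scale too the count filter was applied again, so the regions tested may differ. Adjusted over the implied 49696 tested regions 0 passed (smallest adjusted p at most 0.746, counting the listed regions alone, with all 268 at an unadjusted p under 0.005). DESeq2 called 41 with its own size factors (57 at an unadjusted p under 0.05) and 0 at the recovered library sizes (185). With its own size factors the largest higher region, near GPR153, did not pass (DESeq2 adjusted p = 0.174). The best covered lower region, in PMF1, passed (DESeq2 adjusted p = 1.61e-05). These factors also moved the MYLIP region from a log2 fold change of 0.69 to -0.56. The 41 are not split by direction here.

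The share of higher regions was 13.2 percentage points larger in ATRA than in DMSO (two-sided Fisher's exact p = 0.00046), and 3.09 points larger on the normalized count scale (p = 0.430). In the simulated unchanged regions it was 5.72 points larger, a value whose sampling error was not measured. All regions of a treatment share 1 control library and are not independent replicates. The Fisher p-values of this paragraph, and the intervals on the shares given above, therefore do not measure the spread between libraries. Regions inside a gene made up 249 of 323 (77.1%) in DMSO and 218 of 268 (81.3%) in ATRA. In DMSO the share of higher regions was 65.5% inside genes and 67.6% outside (odds ratio 0.910, two-sided Fisher's exact p = 0.781, Benjamini-Hochberg adjusted p = 0.781 over both treatments). In ATRA it was 82.6% inside and 64.0% outside (odds ratio 2.66, exact p = 0.00629, adjusted p = 0.0126), but on the normalized count scale 70.2% and 64.0% (odds ratio 1.32, exact p = 0.401, adjusted p = 0.781).

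Both hairpins lay on the same side of the control in 323 of 323 regions in DMSO and 268 of 268 in ATRA (251 on the normalized count scale). They share a control and the regions were selected by p, and simulated unchanged regions that passed the same p gave 100% in both treatments. As a check against 1 library deposited under both labels, the chi-square per degree of freedom between their reads was 1.94 in DMSO and 2.22 in ATRA, where counting error alone gives values near 1. The log2 reads of the hairpins correlated across regions, which are not independent replicates, with r of 0.86 and 0.87.

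**Figure D3:**
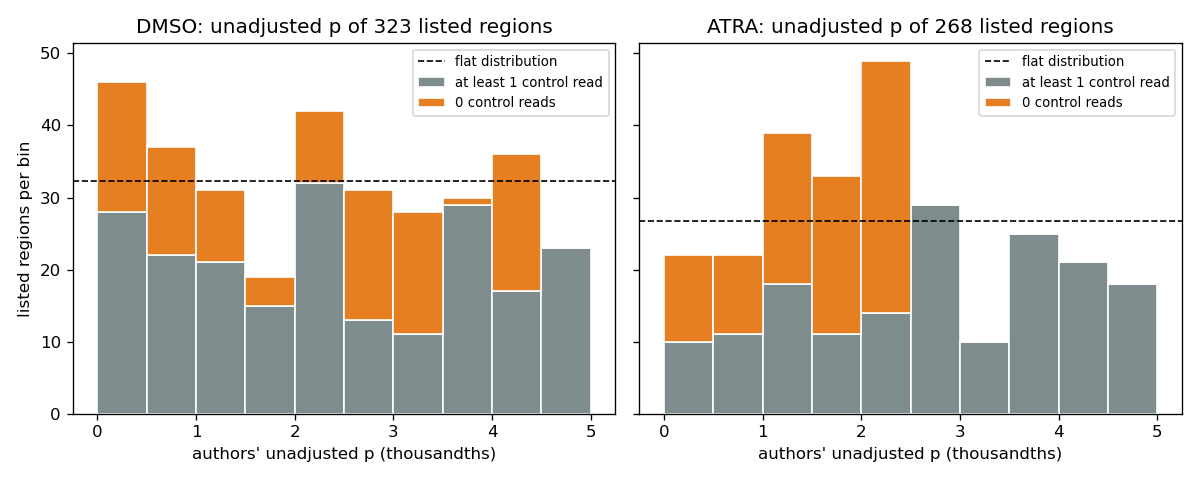
Number of listed regions per bin of the unadjusted p in the authors' deposited table (x axis, in thousandths), for DMSO (left) and ATRA (right), with regions of 0 control reads in orange, the others in grey and a flat distribution as a dashed line. In DMSO 54.2% of the regions lie under 0.0025 and in ATRA 61.6%.

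Regions of EFNA5, an ephrin gene (chromosome 5, 106724909 to 106725064), and CDH13, the T-cadherin gene (chromosome 16, 83480548 to 83480634), were listed in both treatments at identical coordinates and were higher in both. EFNA5 was 7.27-fold higher in DMSO (1.87 to 62.3) and at least 3.02-fold in ATRA, and CDH13 at least 2.69-fold and at least 2.61-fold. These bounds are against the floor, and the exact lower limits, which also cover the knockdown reads, are smaller. For CDH13 in ATRA the exact lower limit was 1.92 on the fold change scale. On the normalized count scale it was 0.958, so no change lies within that interval. The knockdown by treatment interaction was called in neither (edgeR's quasi-likelihood test, adjusted p = 0.602 for EFNA5 and 1.00 for CDH13). It is poorly determined there, since the ATRA control had 0 reads in both regions and the DMSO control at most 2. These 2 shared regions compare with 1.74 for independent lists among 49696 regions (exact hypergeometric p = 0.521). By gene, 11 were listed in both. GPRC5A, a retinoic acid inducible receptor gene, had regions 253 bp apart, at least 2.56-fold higher in DMSO and at least 3.16-fold in ATRA. PTPRN2, DGKB, TSPAN8, AKAP7 and SEL1L were also higher in both, but at different places, with the regions of each gene 47038 to 264826 bp apart. On the normalized count scale, however, the SEL1L region in ATRA was lower and the ATRA regions of AKAP7 (1.34-fold, edgeR adjusted p = 0.496) and PTPRN2 (6.16-fold, adjusted p = 0.110) did not pass the test. MLPH, BCL7A and IRS1, the insulin receptor substrate gene, went in opposite directions, at different regions of each gene: IRS1 was 7.47-fold higher in DMSO (1.93 to 64.0) and 5.03-fold lower in ATRA (2.57 to 10.3). The 8 genes in the same direction compare with 6.60 for independent directions. Across these 11 genes, which are not independent replicates, the log2 fold changes in the authors' deposited table had Pearson r = -0.39 (permutation p = 0.205, adjusted 0.205 over 2 relations) and Spearman correlation = -0.65 (permutation p = 0.0373, adjusted 0.0746), and r was -0.19 without the 2 genes farthest from the median. The CDH13 region in ATRA and the GPRC5A region in DMSO were under the count filter and were not tested. Values for regions with 0 control reads depend on the prior count of the fit.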

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

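The test of the difference between treatments was not among those fixed before the data were examined, and the tests on the normalized count scale, in simulated regions, in well-covered regions and of the interaction were chosen after the result was seen. The share of listed regions with higher accessibility in the knockdown was 79.1% in ATRA and 65.9% in DMSO, and the test of that difference (13.2 percentage points, two-sided Fisher's exact p = 0.00046) singled it out. That p treats regions as independent although those of a treatment share 1 control library, so it does not measure the spread between libraries. In simulated unchanged regions that passed the same p the difference was 5.72 points (253 regions in DMSO and 265 in ATRA). The simulation was not repeated with other random draws, so the sampling error of these 5.72 points is not known and they may not differ from 0. On the scale of the authors' normalized counts the observed difference was 3.09 points (p = 0.430), and among higher ATRA regions with at least 20 control reads, such as those at PABPN1, MYLIP and SEL1L, the median log2 fold change was 0.95 on the fold change scale and -0.048 on the normalized count scale. Both values follow from the constant shift of 1.01 log2 units between the scales, so they show that the pattern depends on the scale and are no evidence that scaling of the ATRA control, or a broad loss of its reads at well-covered regions, is the cause. The well-covered ATRA regions also include 37 of 86 that were lower in the knockdown, with a median log2 fold change of -1.74 (-2.74 on the normalized count scale). Of the 101 well-covered DMSO regions, 80 were lower, with a median of -1.10 (-1.28 on the normalized count scale). The other 21 were higher, with a median of 1.06 (0.88). These technical explanations cannot be told apart from a different effect of the knockdown in differentiating cells, because there is 1 control library per treatment and the interaction can be tested in 2 shared regions alone, where edgeR called 0 of 2 (0 at an unadjusted p under 0.05).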

How the results depend on the processing

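The normalized count scale, the adjustment over the implied number of tested regions, DESeq2 at the recovered library sizes and the restriction to regions with at least 1 control read were chosen after the data were seen. The count of 261 called regions in DMSO was 159 at an adjusted p under 0.01, 148 above the median abundance (fewer regions tested), 0 with DESeq2 (81 at an unadjusted p under 0.05), 0 with DESeq2 at the recovered library sizes (74) and 0 over the implied number of tested regions. The count of 257 in ATRA was 134 above the median abundance, 148 on the normalized count scale, 41 with DESeq2 (57 at an unadjusted p under 0.05), 0 with DESeq2 at the recovered library sizes (185 at an unadjusted p under 0.05) and 0 over the implied number. The direction of the 41 DESeq2 calls was not counted here. Both counts of 0 over the implied number rest on the p-values together with the number of tests. The smallest p was 1.58e-05 in DMSO and 2.26e-05 in ATRA. With ranks among the listed regions alone, a listed region would have passed among at most 6211 tests in DMSO and at most 3332 in ATRA. The implied numbers were 54588 and 49696. Regions not analysed here could raise those ranks, so neither these limits nor the counts of 0 are firm. The percent higher in DMSO was 73.1 at an absolute log2 fold change of at least 1, 55.9 above the median abundance and 47.9 with at least 1 control read, which reverses it, because all 112 regions with 0 control reads are higher. In ATRA it was 69.0 on the normalized count scale and 66.5 with at least 1 control read. The odds ratio for regions inside genes in ATRA was 1.32 on the normalized count scale. Counting by gene symbol gave 11 shared items in place of 2 regions. The SEL1L region in ATRA reversed, to -0.30 on the normalized count scale and -0.55 with DESeq2. The normalized count scale shifts all ATRA values alike by 1.01 log2 units; the cause of the other moves, beyond the stricter threshold and the way of counting, was not tested. Of the 88 named regions, 86 were called and 2 were under the count filter. Of the 86, 80 kept direction and call on the normalized count scale, 5 kept direction alone and 1 reversed; with DESeq2 these were 9, 76 and 1. Leaving out either hairpin leaves 1 library against 1 and no test; the percent higher, 65.9 in DMSO and 79.1 in ATRA, could not move, since both hairpins lie on the same side in each region, so it says nothing about stability. Within a treatment no paired analysis was possible because the control carries no hairpin number. Across treatments, the interaction in the 2 shared regions, added after the data were seen, called 0 of 2 without the block, 0 with the hairpin as a replicate block and 0 on the normalized count scale (0 at an unadjusted p under 0.05 in each). The pseudocount alternative did not apply to counts, and the fold changes at 2 shared positions gave no correlation. Depth limits most regions: the median was 12.3 reads per library in DMSO and 11 in ATRA.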

Other observations

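The tests of p-values under 0.0025 and 0.0005, of shared regions against chance and on the normalized count scale were chosen after the results were seen, and the regions in the first 2 paragraphs were chosen after their values were seen. The listed regions with most reads carry the smallest counting error. In DMSO the best covered lower regions were in FCHSD2, an endocytosis gene (436 and 508 reads against 524, 1.37-fold lower, 1.23 to 1.53), then in ACAP2, then 868 bp from DUSP6, the ERK phosphatase gene (301 and 276 against 332, 1.42-fold lower, 1.24 to 1.63), and in RRM2, the ribonucleotide reductase subunit gene, CKAP2 and TMX4. None of these 6 passed edgeR's quasi-likelihood test on the fold change scale (adjusted p from 0.0595 to 0.0683 over the listed regions), while all 6 passed it on the normalized count scale (adjusted p from 0.00172 to 0.00204). The best covered higher regions in DMSO were in SH3RF3 (245 and 272 against 134, 1.56-fold higher, 1.29 to 1.90), TMED7, RALGAPB, LMAN1, the cargo receptor gene for coagulation factors, SNRPF and CCDC124. In ATRA the best covered lower regions were in PMF1, a kinetochore gene (183 and 177 against 239, 1.61-fold lower, 1.36 to 1.90), and MTRNR2L6, whose sequence resembles mitochondrial ribosomal RNA so that its reads are uncertain, then at NARF, SULT2A1, ST8SIA1 and ZNF770. The best covered regions higher in ATRA on the fold change scale were in PABPN1, MYLIP, SEL1L, RNASET2, NOP56 and RNF170, and all 6 were lower on the normalized count scale. The region in PABPN1, a poly(A) binding protein gene, passed edgeR's test as higher on the fold change scale (adjusted p = 0.00993) and as lower on the normalized count scale (log2 fold change -0.37, adjusted p = 0.0439).

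Genes with listed regions in both directions were RBMS1 in DMSO and CD247, DLG2, KALRN, KCNJ5 and PITPNC1 in ATRA. In PITPNC1, a phosphatidylinositol transfer protein gene, a region had 11 and 22 reads against 0 (at least 4.53-fold higher) and another 32 and 20 against 52 (2.43-fold lower, 1.62 to 3.64). In KALRN a region had 10 and 17 reads against 0 (at least 3.71-fold higher) and another 5 and 1 against 15 (6.07-fold lower, 2.23 to 19.1).

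Few regions were listed in both treatments. The 2 shared regions lie under 5, the upper end of the 95% range for lists drawn independently from 49696 regions, and the 323 and 268 listed regions compare with 273 and 248 that p under 0.005 would give by chance among the implied numbers tested, so many listed regions may be chance listings. In DMSO 54.2% of listed p-values lay under 0.0025, where a flat distribution gives 50% (exact binomial p = 0.148), although 46 lay under 0.0005 against 32.3 for a flat one (exact p = 0.0154), and 55.9% lay under 0.0025 among regions with at least 1 control read. In ATRA 22 lay under 0.0005 against 26.8 (exact p = 0.361) and 61.6% lay under 0.0025 (exact p = 0.000183) but 38.3% among regions with at least 1 control read. All 101 ATRA regions with 0 control reads lie under 0.0025, and each holds at least 19 summed knockdown reads. Regions with 0 control reads and fewer knockdown reads, which would have a larger p, may have been left out by a lower limit on abundance. The 61.6% therefore cannot be weighed against a flat distribution. Treatment-specific effects of the knockdown stay open, and the numbers tested are inferred and include regions farther than 10 kb from a gene, which were not analysed here, so both chance comparisons lean towards a high count by chance for the listings and a low count for the overlap.

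Regions with 0 control reads made up 112 of 323 (34.7%) in DMSO and 101 of 268 (37.7%) in ATRA, with a median of 21 summed knockdown reads, while 0 regions had 0 reads in both knockdown libraries. That last count was also 0 in both treatments among simulated unchanged regions that passed the same p, so it does not separate listed from unchanged regions. The comparison of 2 knockdown libraries with 1 control library may favour such regions. Among simulated unchanged regions that passed the same p, 18.6% and 18.9% had 0 control reads, between the bounds of 10% and 25% set before the simulation, so the part of the observed share that the library numbers give cannot be told apart from a true gain of accessibility. The simulation used the listed regions' mean counts and a dispersion of 0.05, and other values were not tried. It set no lower limit on abundance, while the listed regions may have had one, so the shares are not fully comparable. Such regions were narrower, with a median width of 96.5 against 193 bp in DMSO and 103 against 258 bp in ATRA.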
